A study of Mus musculus with 2 samples.

How the data were processed

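The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the histone lysine demethylase LSD1 in C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is withdrawn. There was 1 LSD1 ChIP library and 1 input library, which is sheared chromatin sequenced without an antibody. Per the labels' protocols, cells grew in medium with 25 mM glucose and 10% fetal bovine serum and were then switched to 2% horse serum for 48 h. Chromatin was fixed with formaldehyde and a longer protein crosslinker, disuccinimidyl glutarate, and was sonicated in 2 steps. Libraries were amplified for 8 to 10 cycles and were 170 to 500 bp long. The longer crosslinker can also capture LSD1 held to DNA through partner proteins, so a peak does not show direct contact.

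Reads were aligned with BWA to the mouse build mm9, per the submitters' processing notes, which name no version. The peaks were called with MACS run in Galaxy, per the file headers, and the deposited list compares the ChIP library with the input library. The MACS version, its settings and any filter on duplicate or multiply mapped reads are not given in the sources used here. The deposited list gives for each peak a position and 1 score, which the authors' peak caller assigned. The scale of the score is not stated, so it was used only to describe, rank or filter peaks within this list. The file holds no read numbers, so the depth of both libraries is unknown and no value carries a read-based interval. Because 1 list came from 1 ChIP and 1 input library, there is no replicate error anywhere in these results. Tests across peaks describe this list and cover counting error only. Peaks of 1 list are not independent replicates.

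Peak positions are given 1-based in mm9. The gene table in hand was of another build (GRCm38), so its coordinates were not used, and a genome sequence and gene annotation of mm9 were not used here. The planned analyses of genomic location, promoters of fixed gene lists, motifs and base composition were therefore not run, and no gene is named. By the rule set for that case, the peaks named are the 10 with the highest score and the 5 widest, together with the densest 100 kb window.

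The 19 autosomes and X entered the chromosome and clustering tests. The span of a chromosome is the distance from its first to its last peak. Peaks per chromosome were compared with its share of the summed span by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over 20 chromosomes and exact (Clopper-Pearson) 95% intervals. Clustering was measured as the share of peaks whose nearest neighbouring start lay within 10 kb. It was compared with 1000 random placements of the starts within each chromosome's span (permutation test, one-sided). These placements also covered sequence in which no read can be mapped, since gaps in mm9 were not used here. Score and length were related by Spearman's and Pearson's coefficients with 100000 permutations, two-sided. Choices fixed before the data were examined were the main tests, the naming rule, and the alternatives using peaks scoring at or above the list's median, distances of 1 and 50 kb, peaks within 10 kb counted once, and the list without its 1% widest peaks. Chosen after seeing the data were the definition of dense regions (at least 20 peaks whose starts follow each other within 50 kb, picked after chains of at least 10 peaks within 10, 20 and 50 kb had also been looked at), the class of peaks of 2 kb or more, the permutation of 5 Mb blocks between chromosomes, placement within 1 Mb windows, joining peaks across gaps of up to 1 kb, and the rule for raised stretches.

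The chromosome and clustering tests were also tested on simulated data. With 11492 peaks placed at random, the chromosome test called 2 of 2000 chromosomes. It called a chromosome raised 1.2-fold in 83 of 100 simulations and one raised 1.5-fold in 100 of 100. In these simulations peaks were placed independently of each other, as the binomial test assumes. The peaks of the list lay in groups, so these rates do not hold for the list itself. The clustering test called 0 of 20 simulations without planted neighbours and 20 of 20 with 200 planted neighbours. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.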

Results

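LSD1 (KDM1A) is a chromatin enzyme that removes methyl groups from histone H3. The study asked where in the genome LSD1 sits in C2C12 myoblasts 48 h after the start of differentiation. The comparison was LSD1 ChIP against input, with 1 library each.

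The authors' deposited list held 11797 non-overlapping LSD1 peaks covering 6.68 Mb of mm9. The peaks were short: the median length was 441 bp, the lower and upper quartiles were 360 and 615 bp, and the range was 150 to 21363 bp. Of all peaks, 746 were 1 kb or longer and 141 were 2 kb or longer. Scores ranged from 50.01 to 3100, with a median of 78.25 and an upper quartile of 119.41, and 25 peaks had a score of 1000 or more. The 19 autosomes and X held 11492 peaks, Y held 1 peak, and 304 peaks lay on 9 unplaced or unlocalised sequences. Over the autosomes and X the density was 4.48 peaks per Mb. Read depth is unknown, so how many weaker sites went uncalled cannot be estimated.

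Longer peaks had higher scores. The authors' peak caller set both values from the same libraries, so the relation may come from the calling and is no evidence about LSD1 binding. With the list cut at the quartiles of the score, the median length was 337 bp in the lowest class, 390 and 468 bp in the next ones and 681 bp in the top class. Across the 11797 peaks, Spearman's rho was 0.69 and Pearson's r was 0.62 (permutation tests, two-sided, each p = 1e-05, the smallest that the resamples can give). These 2 coefficients were the only ones computed on the full list.

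**Figure D1:**
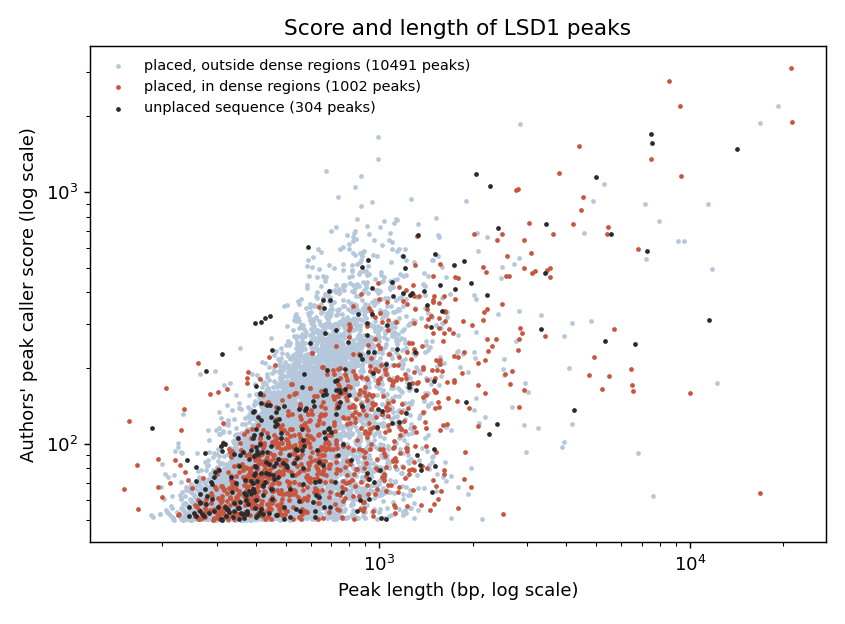
Each point is 1 LSD1 peak, with its length in bp on the x axis and the authors' score on the y axis, both on log scales. Colours mark the 10491 peaks on placed chromosomes outside dense regions, the 1002 in dense regions on placed chromosomes and the 304 on unplaced sequence. Peaks of 2 kb or more made up 7.72% of the 1023 peaks in all dense regions and 0.515% of the peaks on placed chromosomes outside them.

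LSD1 peaks were most frequent on chromosome 15 and least frequent on chromosomes 7 and 9. Chromosome 15 held 1044 peaks, 10.4 per Mb, which was 2.33 times its share of the span (95% interval 2.20 to 2.47, exact binomial test, adjusted p = 6.67e-133). Chromosome 8 held 833 peaks at 1.45 times its share, chromosome 4 held 886 at 1.34 times, chromosome 10 held 729 at 1.28 times, and chromosome 13 held 589 at 1.13 times. Chromosome 7 held 408 peaks, 2.75 per Mb or 0.614 times its share (interval 0.557 to 0.676), and chromosome 9 held 354 at 0.654 times.

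In all, 5 chromosomes lay above their share, 11 lay below it and 4 (1, 3, 17 and X) did not pass the exact binomial test. These ratios are relative to a total that includes chromosome 15, so its excess lowers the ratios of all other chromosomes. A ratio a little below 1, such as 0.894 for chromosome 12 or 0.884 for chromosome 16, therefore does not by itself show a lack of LSD1 peaks. The binomial test treats peaks as independent, and they lay in groups. When 5 Mb blocks were permuted between chromosomes, chromosome 15 alone passed (10.4 ± 5.36 peaks per Mb, SD over 20 blocks, against a mean of 4.24 in the other blocks, permutation test, adjusted p = 0.0012). This permutation treats neighbouring blocks as independent. High density ran over more than 1 block in places, such as 50 to 69 Mb on chromosome 15, so its p-values can be too small. Dense regions held much of the excess of chromosomes 4 and 13. Without those regions the ratios were 0.946 for chromosome 4 (adjusted p = 0.216, exact binomial test; 1.12 and adjusted p = 0.00457 when dense regions were chains of at least 10 peaks within 10 kb) and 0.983 for chromosome 13 (adjusted p = 0.725). Chromosome X, at 0.937 times its share with all peaks, was at 0.788 times without dense regions (adjusted p = 1.74e-08, exact binomial test), which did not pass when blocks were permuted (permutation test, adjusted p = 0.160). The copy number of the chromosomes in these cells is not known from the files.

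**Figure D2:**
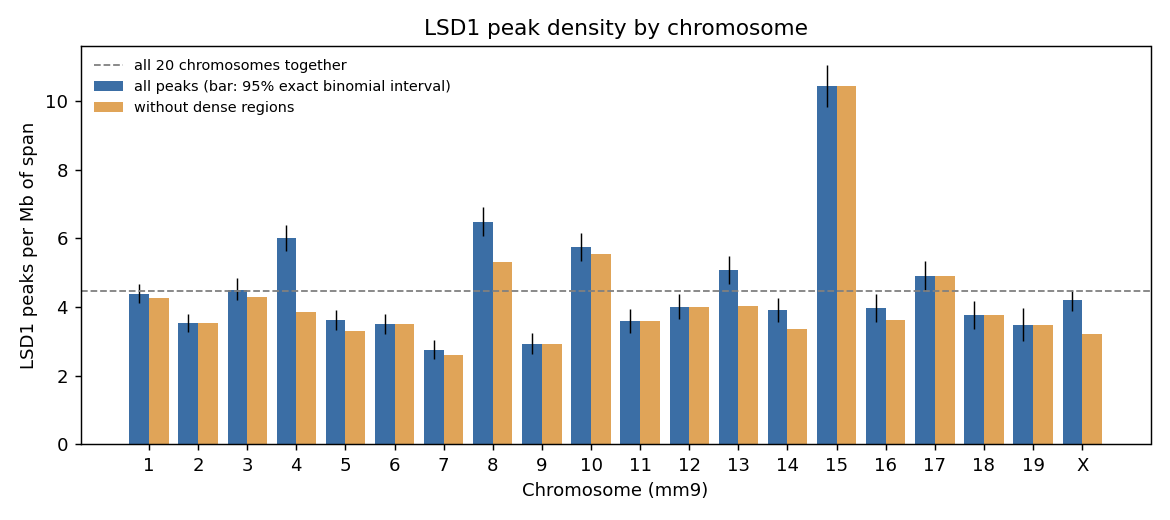
Bars give LSD1 peaks per Mb of span for each mm9 chromosome, with all peaks in blue (black lines: 95% exact binomial intervals, counting error only) and without dense regions in orange. The dashed line marks 4.48 peaks per Mb over all 20 chromosomes, and chromosome 15 stands at 10.4.

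The peaks of chromosome 15 were spread unevenly along it. Raised stretches were taken as runs of at least 5 windows of 1 Mb whose running mean over 5 windows was at least 2 times the mean of all windows (4.45 peaks). Chromosome 15 had 4 such stretches: 3 to 13 Mb with 15.1 peaks per Mb, 21 to 37 Mb with 12.6, 38 to 45 Mb with 14.1 and 50 to 69 Mb with 16.8. The rest of the chromosome held 5.57 per Mb. Chromosome 8 had stretches at 80 to 91 Mb with 24.7 peaks per Mb, 93 to 101 Mb with 13.8 and 70 to 75 Mb with 95 peaks in all, against 3.39 per Mb in its rest. Chromosome 4 carried 346 of its 886 peaks in 1 stretch from 143 to 150 Mb, and 91% of those lay in dense regions. Chromosome X carried 137 of its 686 peaks from 28 to 34 Mb, and 175 more in its first 10 Mb. Chromosomes 1, 3, 10, 13 and 14 had 1 or 2 stretches each. The rule was set after the profile was seen, so the stretches were not tested.

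**Figure D3:**
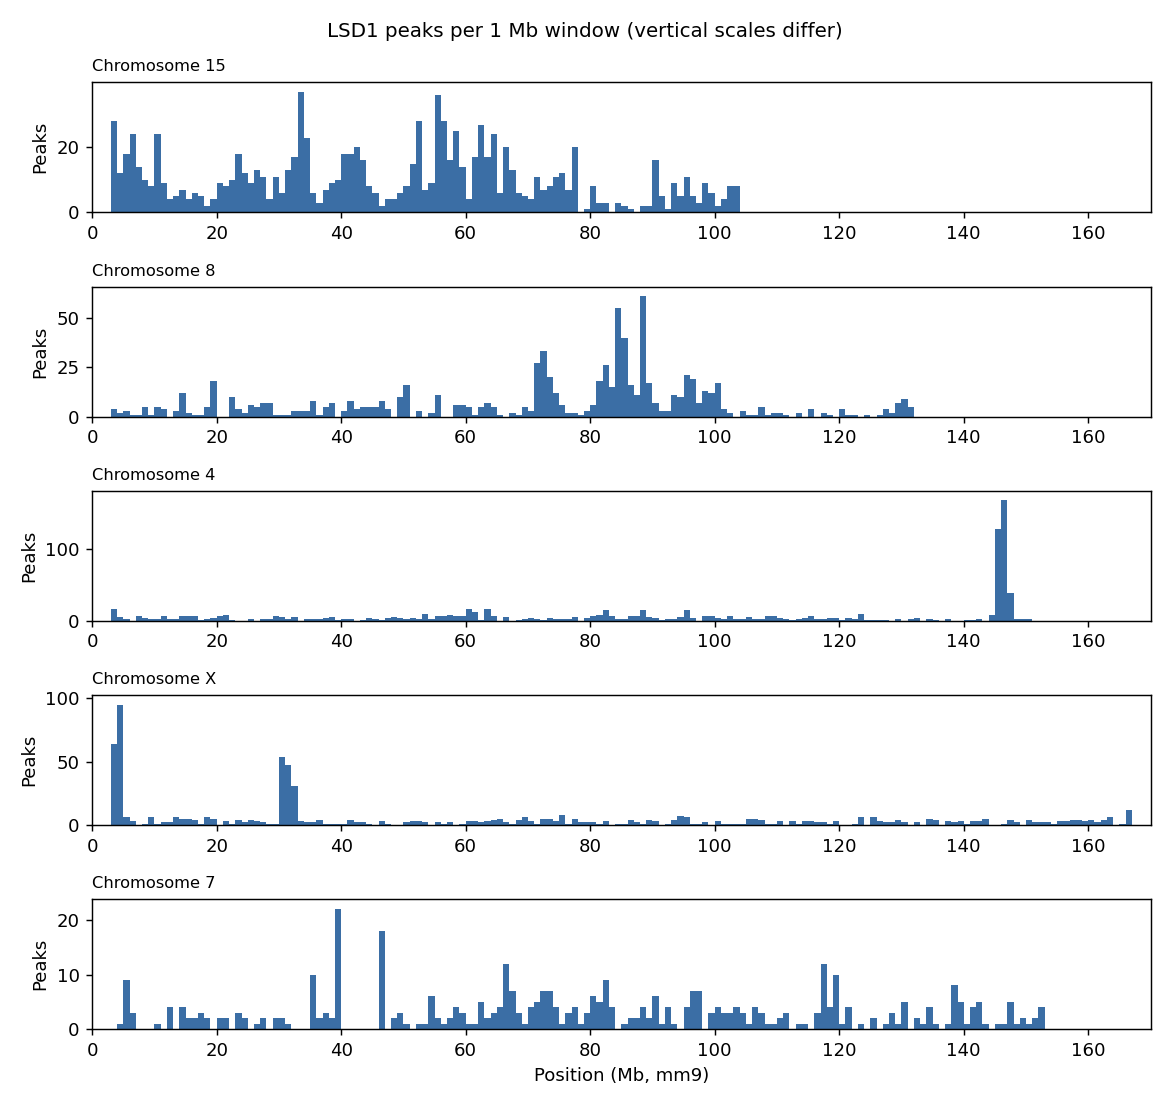
Bars give the number of LSD1 peaks in each 1 Mb window along chromosomes 15, 8, 4, X and 7, with position in Mb (mm9) on the x axis and a vertical scale of its own for each chromosome. On chromosome 15 high windows lie in 4 separate stretches between 3 and 69 Mb, and chromosomes 4 and X carry narrow towers, the highest of 167 peaks on chromosome 4.

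LSD1 peaks lay close to each other far more often than random placement gave. Of the 11492 peaks on the autosomes and X, 3853 (33.5%, 95% exact interval 32.7 to 34.4%) had a neighbouring start within 10 kb. The interval treats peaks as independent, but a peak and its neighbour are counted together, so it is too narrow. Random placement gave 9.44% ± 0.38 (SD over 1000 placements), a ratio of 3.55 (permutation test, one-sided, p = 0.001, the smallest that 1000 placements can give). Within 1 kb the shares were 8.08% and 0.99%, a ratio of 8.16. Of the 2581 windows of 1 Mb, 258 held no peak, and the variance of the number per window was 10.8 times its mean.

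The groups included 25 dense regions with 1023 peaks, 8.67% of the list and 15.3% of the covered sequence. The largest lay on chromosome 4 at 146322973 to 147195662, with 169 peaks over 873 kb, and it held the densest 100 kb window, 146910708 to 147010707, with 40 peaks. The next was also on chromosome 4, at 144983639 to 145452117, with 87 peaks. A region on chromosome 14 at 43917005 to 44201712 held 66 peaks, one on chromosome 8 at 71947983 to 72121062 held 53, and one on chromosome 13 at 12833149 to 13104213 held 52. Chromosome X had 4 dense regions with 159 peaks together. Chromosome 15 had none. Peaks in dense regions had a median length of 627 bp and a median score of 90.97, against 431 bp and 76.91 on placed chromosomes outside them.

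The highest-scoring peaks were mostly long. The top score, 3100, belonged to a 21184 bp peak on chromosome X at 32095098 to 32116281. The next 3 were on chromosome 4 at 146017370 to 146025962 (score 2769.9), chromosome X at 4237550 to 4246830 (2207.16) and chromosome 8 at 19989454 to 20008628 (2199.37). Chromosome 5 followed with peaks at 14970388 to 14991750 (1906.29) and 15112661 to 15129493 (1888.08), and chromosome 8 with a peak at 19904984 to 19907813 (1870.01). The unlocalised sequence of chromosome 8 held peaks at 708307 to 715787 (1707.35) and 373557 to 381120 (1570.33). Of these 10 peaks 9 were 2 kb or longer, 5 lay in dense regions and 2 on unlocalised sequence. The exception in length was a 993 bp peak on chromosome 3 at 37704336 to 37705328 (1655.84). The 5 widest peaks included 4 of the same 10. The other one, on chromosome 5 at 15017679 to 15034563, was 16885 bp long with a score of 63.68.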

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

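Peaks on unplaced or unlocalised sequence entered none of the chromosome or clustering comparisons and were set apart for that reason alone. There were 304 of them, and since these sequences are part of the build, peaks there are no departure from an expected value. They lay on 9 sequences, with 185 on the pool of sequence assigned to no chromosome, 35 on sequence of chromosome 1 and 34 on that of chromosome 8. Their median score was 93.96 against 77.9 for all other peaks, a difference of 16.06 (permutation test, two-sided, p = 1e-05, the smallest that the resamples can give). Their median length was higher by 56.5 bp (permutation test, p = 0.00024). Without the 21 peaks of the dense region on sequence of chromosome 8, the differences were 12.98 in score (permutation test, p = 9.0e-05) and 31 bp in length (permutation test, p = 0.031). The sequences differed: the median length was 448 bp on the pool assigned to no chromosome, and the median score was 58.46 on sequence of Y and 72.56 on that of chromosome 1, below that of all other peaks. These tests were chosen after the values were seen, and they treat peaks as independent although the peaks lie in groups.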

How the results depend on the processing

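The length and score relation kept its direction with p = 1e-05 for peaks scoring at or above the median (rho 0.59), without the 1% widest peaks (0.69) and without dense regions (0.70). Clustering stayed above random (permutation tests, each p = 0.001, the smallest possible) at 7 alternatives, with ratios from 1.54 (50 kb) to 8.16 (1 kb). By construction, 5901 peaks score at or above the median. With the binomial test, 4 chromosomes lay above and 9 to 10 below their share under the other settings. With the block permutation, chosen after seeing the data, 1 lay above and 0 below, and without dense regions 1 above and 1 below, chromosome 7 (adjusted p = 0.0413). Chromosomes 4 and 13 reversed to 0.946 and 0.983 without dense regions, which hold 35.6% and 20.7% of their peaks, and chromosome 13 to 0.967 with peaks within 10 kb counted once. Under at least 1 other setting, chromosomes 11, 12, 16 and 18 lost their calls below their share. Chromosome 17 gained a call above its share with peaks within 10 kb counted once (1.17, adjusted p = 0.0065, exact binomial test), and again without dense regions, of which it has none. X gained one below it among peaks scoring at or above the median (0.775, exact binomial test, adjusted p = 1.15e-05), with peaks within 10 kb counted once (0.768, adjusted p = 1.18e-08) and without dense regions. Of the calls above, chromosome 4 fell to 1.03 (adjusted p = 0.492, exact binomial test) with peaks within 10 kb counted once, and chromosome 13 to 1.12 (adjusted p = 0.0702) among peaks scoring at or above the median. With dense regions defined instead as at least 10 peaks within 10, 20 or 50 kb (48, 60 and 76 regions), the ratio of chromosome 15 was 2.47, 2.57 and 2.32, that of chromosome 4 was 1.12, 0.952 and 0.962, and that of chromosome 13 was 1.02, 0.975 and 0.929. None of the values below 1 for chromosomes 4 and 13 passed the binomial test. The expected share by assembled length outside gaps was not run, nor were the alternatives for location, promoters, motifs and base composition, because no mm9 genome was used here. No paired analysis was possible because each group had 1 library and the list gives no values per sample. For the same reason no replicate could be left out.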

Other observations

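On the autosomes and X, 4724 peaks (41.1%) had no other start within 50 kb, with a median length of 408 bp and a median score of 72.65, and 4 of them were 2 kb or longer. The 10 highest of these, a choice made after the list was seen, were 632 to 1137 bp long with scores from 571.73 to 1358.73. The first was on chromosome 3 at 130757051 to 130758042 (score 1358.73), followed by chromosome 17 at 16355374 to 16356244 (1159.03), chromosome 8 at 63251847 to 63252795 (916.9) and chromosome 11 at 121363138 to 121363965 (691.17). Chromosome 17 held 2 more, at 84984100 to 84985121 (615.41) and 4626043 to 4626674 (592.59).

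Dense regions were not of 1 kind. On chromosome 5, at 14871086 to 15045888, 25 peaks with a median length of 2312 bp covered 63% of the region. On chromosome 8, at 84225567 to 84602257, 26 peaks with a median length of 396 bp and a median score of 65.2 covered 2.98%. On chromosome X, 41.1% (95% exact interval 37.4 to 44.9%) of peaks scored at or above the list's median.

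The following tests were run on patterns seen in this list. Those for tandem arrays, for wide peaks on unplaced sequence and both tests for chromosome 15 were chosen after the result was seen. Placement within 1 Mb windows and joining of peaks were chosen after seeing the list, with the prediction written before their own result.

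The first pattern is the excess on chromosome 15. A few dense groups do not hold it: its ratio was 2.24 (95% interval 2.10 to 2.40) with peaks within 10 kb counted once, and 2.32 without chains of at least 10 peaks within 50 kb, which removed 139 of its 1044 peaks. The excess was broad: 18 of 20 blocks of 5 Mb (90%, exact interval 68.3 to 98.8%) lay above the median block of the other chromosomes. This interval treats neighbouring blocks as independent, so it can be too narrow. A candidate explanation, as a hypothesis, is extra copies of most of chromosome 15 in these cells. Extra copies would raise the number of ChIP reads and of input reads alike, so the ratio of ChIP to input need not rise. The larger number of reads could still bring weaker sites past the caller's threshold. The share of raised blocks is what such a gain would give, but a broad excess from denser LSD1 binding would give it too. A block counted as raised when it lay above 3.4 peaks per Mb, so the share cannot tell these causes apart. Blocks ranged from 1.4 to 21 peaks per Mb, with 12.6 to 16.8 per Mb in the raised stretches and 5.57 in the rest. This unevenness cannot decide for or against an even gain, which would scale a profile that may already be uneven. The stretches were also picked for their high density from the same list. Chromosomes 1, 3 and 14, which had no excess, held raised stretches too, but of another kind. Those were 5 or 6 Mb long, with 41.5 to 64.1% of their peaks in dense regions. The stretches of chromosome 15 were 7 to 19 Mb long and held no dense region. Extra copies and denser LSD1 binding both stay open, as untested, since input read depth was not analysed here.

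The second pattern is that peaks lie close together, for which differences in density between megabases account for part of it: placement within each peak's own 1 Mb window gave 18.6% with a neighbour within 10 kb, and the observed share was 1.81 times that (permutation test, p = 0.001); windows that owe their density to dense regions take up part of the clustering, and without those regions the ratio was 2.14. Splitting of broad regions into several calls is not the whole cause either, as the ratio to random placement was 2.80 with peaks joined across gaps of up to 1 kb, against 3.55 as called. For some of the dense regions a candidate explanation is multi-copy or incompletely assembled sequence. Its ground is that peaks of 2 kb or more were 12.1 times as frequent on unplaced sequence as on placed chromosomes outside dense regions (Fisher's exact test, p = 8.05e-14). With all unplaced peaks kept, the ratio was 9.81 to 18.9 under the other definitions of dense regions. Under the main definition, without the 1 dense region on unplaced sequence, the ratio was 5.49 (Fisher's exact test, p = 0.000203). Peaks of 2 kb or more also made up 7.72% of peaks in dense regions against 0.515% on placed chromosomes outside them (Fisher's exact test, p = 3.77e-49). The Fisher tests treat peaks as independent although they lie in groups, so their p-values can be too small. On unplaced sequence, 11 of the 19 peaks of 2 kb or more lay in its 1 dense region. In dense regions such peaks were unevenly spread: regions on chromosome 5 and on unlocalised sequence of chromosome 8 held 24 of the 79. The share was 5.63% in the other 23 regions. In 9 regions with 273 peaks, among them those of chromosomes 1 and 13, there were none. For those 9, peaks of 2 kb or more give no ground for this explanation, but their absence does not exclude it. The median peak length in those 9 ranged from 384.5 to 634 bp, against 431 bp on placed chromosomes outside dense regions. Whether the dense regions are tandem copies of 1 array cannot be told apart from chance. Pairs of consecutive spacings recurred 17 times within 50 bp, against 11.1 ± 3.37 (SD) with the order shuffled (permutation test, p = 0.0639). With 4 near-exact simulated copies, 40 peaks in all, the test called 20 of 20 simulations, and with 1 copy 0 of 20. Each simulation held 1 region, whereas the test on the list pooled 25 regions. The simulations therefore do not show how well the pooled test finds an array present in only a few regions. Domains that LSD1 occupies densely remain open, as untested.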
